A study of Mus musculus with 18 samples.

How the data were processed

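RNA was sequenced from 18 libraries of sorted mouse lung cells, 3 libraries in each of 6 groups (3 populations by 2 genotypes). The labels state that total RNA was purified with the Qiagen RNeasy Mini kit and that libraries were made with the Illumina TruSeq kit. The deposited table holds RSEM estimated counts, that is, expected counts of reads per gene that are not scaled by library size, and per the submitters' processing notes RSEM 1.2.12 and Bowtie 1.0.1 were used with genome build mm9. The gene annotation, the strand setting, read length, and any filter on reads or genes are not given in the sources used here. Without a stated strand setting, reads from overlapping or antisense genes cannot be told apart, and genes that share reads with close copies are estimates whose split depends on RSEM.

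The table had 23224 genes, of which 3098 were 0 in every library. All sample columns matched 1 sample title each, and no column was left unused. Between 33.16% and 41.56% of the values in a library were not whole numbers, as is usual for RSEM estimates, and all values were rounded to whole numbers before count tests. In 9 genes the same non-whole estimate of at least 10 (more than 0.05 away from a whole number) occurred in at least 3 libraries: Akr1b3, Amd1, Atp6v0c, Btg3, Fam100b, Gm9781, Nutf2, Rmnd1 and Rpl34-ps1. Calls on these genes are treated as uncertain. Libraries of a group were compared with each other by a chi-square statistic over genes. None were identical, and the statistic per gene ran from 21.1 to 414, so no pair was treated as 1 library. Totals ran from 17551293 to 30726994 estimated counts per library. The limit that a count of 0 allows was taken as 3 counts per library, and it covers counting error only, since reads from PCR-amplified libraries without molecular identifiers are not independent molecules.

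The choices described next, including gene lists, tests, alternatives and the rule for naming genes, were made before the data were examined, except where an addition is named. Sample groups came from the sample titles and genotype labels. For each population, knockout was compared with wild type in a fit of its 6 libraries. Populations were compared with each other in the 9 wild-type libraries. The difference of the genotype effect between populations was tested in a fit of all 18 libraries with 6 group means. Each fit used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM normalization, the filterByExpr filter (minimum count 10) and robust dispersion, with Benjamini-Hochberg adjustment at 0.05. This left 14787, 13849 and 15311 genes in epithelial, endothelial and triple-negative cells, 15448 in the population fit and 15924 in the fit of all libraries. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM values used TMM library sizes of the libraries in the comparison, and summed list values were compared by exact permutation tests run in R. Counts per gene and single library, and the estimate of carried-over RNA, used plain library totals.

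A set of 34 gene lists was fixed, covering cell types, cell cycle, vascular, inflammatory and metabolic programmes, reported microRNA targets, neighbours of the deleted cluster and sex-linked genes, and 33 of them entered set tests. The sex-linked list was the one left out, and its genes stayed in the tests of single genes. Lists with at least 4 tested members were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, which gave 33, 32 and 33 tests in epithelial, endothelial and triple-negative cells. A list's median, mean and camera direction differed in sign in 14 of the 98 tests, none of them called (lowest adjusted p 0.199). List tests of the difference between populations were added after the data had been seen. Genes were named by rule: among genes past the threshold, with a mean of at least 1 CPM and no overlap between the groups, the 10 largest changes per direction, and where fewer than 5 passed, the 5 smallest p values per direction under the same conditions, named as not past the threshold. The rule also named the 3 members with the smallest p in each described list, Camk1d, Kras, the deleted microRNA genes and their host transcript, and for each difference between populations the 5 smallest p values with a mean of at least 1 CPM. Predicted, unnamed (clone or accession symbols) and pseudogene entries entered the tests and counts but were passed over in naming. For populations it took genes with a mean of at least 10 CPM, ranked by the smaller of both log2 differences. Other genes named, among them Krt18, Epcam, Myh6, the sex-linked genes and single list members given as examples, were chosen after their values were seen or as markers of other cell types.

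Seed sites were searched in the longest annotated 3′ UTR of each gene in the GENCODE vM21 annotation of GRCm38, a later build than mm9. Genes were therefore joined by name and no coordinates were carried over. Of the 23224 genes, 19828 (85.38%) matched a gene with a 3′ UTR, 18168 by symbol and 1660 by synonym, and the median UTR length was 994 bases. Sites were 7mer-m8 or 8mer matches to miR-145-5p and miR-143-3p. Log2 fold changes were also regressed on site presence with log UTR length and mean expression, and the shift was set against 100 shuffled heptamers.

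The steps were tested on simulated data: counts were drawn from the real means, dispersions and library sizes with 67, 67 and 66 genes changed by a log2 fold of 1, 2 and 3, each gene drawn independently of the others. In epithelial cells (14702 genes) 37.3%, 76.1% and 92.4% of these were called. In endothelial cells (13772 genes) the shares were 61.2%, 86.6% and 95.5%, in triple-negative cells (15217 genes) 4.5%, 64.2% and 89.4%, and for the difference between endothelial and epithelial cells (15847 genes) 6%, 67.2% and 84.8%. Unchanged genes made up 15 of 152 calls in epithelial, 14 of 176 in endothelial and 10 of 115 in triple-negative cells, and with no gene changed 0, 0 and 1 were called. With no gene changed, 4.28%, 4.89% and 4.54% of genes had an unadjusted p under 0.05 by edgeR. The real genotype comparisons had 2.79%, 2.14% and 1.39%, so the simulated shares called may not hold for the real libraries. A 34-gene list shifted by -0.8 had camera p values of 5.51e-18, 4.85e-21 and 4.62e-12 in epithelial, endothelial and triple-negative cells. A simulated seed-site shift of 0.1 was estimated as 0.0934, 0.113 and 0.101.

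Alternatives were DESeq2 size factors in place of TMM, plain library size (populations only), no count filter, a filter at a mean of 5 CPM, the DESeq2 1.42.0 Wald test, limma voom with sample weights, all 18 libraries in 1 fit, the 9 knockout libraries for the population comparison, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Leaving out the 3 Xist-positive libraries together was added after the data had been seen. Replicate numbers recur across groups in the sample titles. In endothelial cells, wild-type and knockout libraries with the same number deviated from their group means together, with correlations across genes of 0.114, 0.272 and 0.604. By the rule of 0.1 for every pair, these numbers were taken as a possible pairing of the endothelial libraries, although the labels do not say what a number shares. The main endothelial tests did not use it. It entered only the alternative with the replicate number as a block and the account of other splits. The pairing is uncertain, since wild-type replicate 1 correlated more with knockout replicate 2 (0.255) and wild-type replicate 2 more with knockout replicate 1 (0.317). The 8mer sites alone and sites in any annotated 3′ UTR were also tried. Tables were handled with python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. The sequencing reads were not analysed here.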

Results

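RNA sequencing was carried out on 3 cell populations sorted by flow cytometry from tumour-bearing lungs of mice with an activating Kras allele. The populations were Epcam-positive cells (called epithelial here), CD31-positive cells (endothelial, CD31 being the product of Pecam1), and cells negative for Epcam, CD31 and the leukocyte antigen CD45 (triple-negative, which the sample titles call fibroblasts). Each population came from mice with an intact miR-143/145 cluster (wild type) and from mice without it (knockout), with 3 mice per genotype according to the design text. This gave 18 libraries in 6 groups of 3, and p-values of single genes measure the spread between these libraries. Camera at its preset correlation treats the genes of a list as nearly independent. Its p-values therefore do not show how well a list difference repeats between libraries. Total estimated counts ran from 17551293 to 30726994 per library. The group means were 20239849 ± 2737825 counts in wild-type and 23444319 ± 6696874 in knockout epithelial cells, 22200912 ± 3228402 and 22521996 ± 1160715 in endothelial cells, and 23327185 ± 3199017 and 23190223 ± 1595223 in triple-negative cells (SD, n = 3). Between 16572 and 18202 genes had at least 1 count. Below, levels are CPM (counts of a gene scaled to a common library total) as mean ± SD of 3 libraries, and log2 fold changes are given ± SE.

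The deleted genes were examined first. Mir143 and Mir145 had 0 counts in all 18 libraries, wild type included, so their values check none of the genotype labels. At these depths a count of 0 allows up to 0.0976 to 0.171 CPM per library, from counting error only. E330013P06, the noncoding host transcript of the cluster, was detected in every group. In triple-negative cells it had 41, 273 and 72 counts in the wild-type libraries and 258, 277 and 177 in the knockout libraries, a log2 difference of 0.94 ± 0.68. It had 3 to 7 counts in wild-type and 10 to 25 in knockout epithelial libraries, and its log2 difference was 1.56 ± 0.49 there and 0.06 ± 0.31 in endothelial cells. None of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 1.0 in each population). Camk1d is a calcium and calmodulin dependent kinase reported as an endothelial target of miR-145. It measured 5.28 ± 0.30 CPM in wild-type and 7.22 ± 1.62 CPM in knockout endothelial cells, with no overlap between the groups after TMM scaling. By plain library totals Camk1d overlapped, being higher in wild-type replicate 2 (109 of 18923815 counts) than in knockout replicate 3 (118 of 21433481). Its log2 difference was 0.45 ± 0.20 in endothelial, 0.48 ± 0.22 in epithelial and 0.32 ± 0.31 in triple-negative cells, again with adjusted p = 1.0 by edgeR in each. Kras, a reported target of miR-143, differed by -0.13 ± 0.08, -0.09 ± 0.09 and -0.17 ± 0.15 in epithelial, endothelial and triple-negative cells.

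The first comparison asked what each sort contained, using the 9 wild-type libraries. Vascular genes were highest in endothelial libraries: Cdh5, the VE-cadherin of endothelial junctions, measured 3275 ± 49.6 CPM there against 25.6 ± 22.8 in epithelial and 327 ± 226 in triple-negative libraries, and all 23 genes of the pan-endothelial list were higher in endothelial cells than in both other populations. Surfactant genes were highest in epithelial libraries. Sftpc, the surfactant protein C of alveolar type 2 cells, measured 41355 ± 7582 CPM against 739 ± 282 in endothelial and 4350 ± 4150 in triple-negative libraries. Of the alveolar type 2 list, 18 of 20 genes were highest in epithelial cells, as were 11 of 14 alveolar type 1 genes (Ager, 1722 ± 242 CPM), 8 of 16 airway genes (the club cell secretoglobin Scgb1a1, 10559 ± 4391 CPM) and 12 of 18 junction and keratin genes. Most matrix genes were highest in triple-negative libraries. Col3a1, a fibrillar collagen, measured 5447 ± 4785 CPM there against 417 ± 167 in epithelial and 69.1 ± 28.7 in endothelial libraries, and 26 of 30 fibroblast and matrix genes were highest there. So were 15 of 17 contractile smooth muscle genes (Acta2, 190 ± 43.5 CPM against 27.5 ± 28.1 and 15.2 ± 4.90) and 11 of 14 pericyte genes (Pdgfrb, 341 ± 78.2 CPM).

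**Figure D1:**
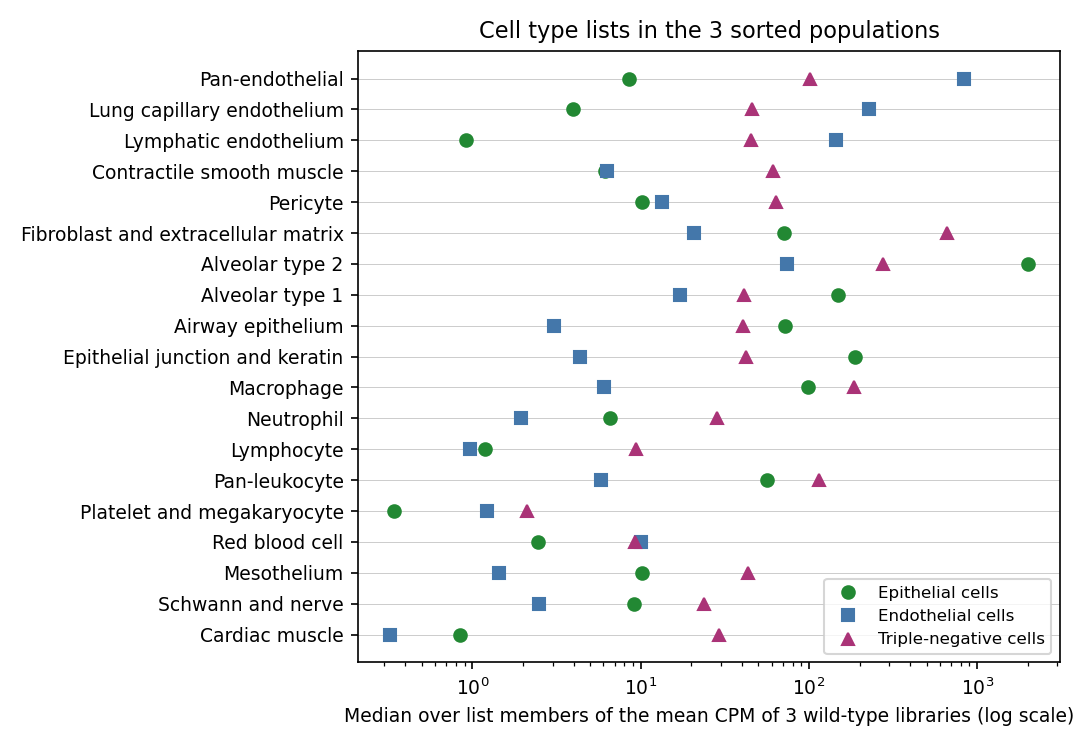
Median over the genes of each cell-type list of their mean CPM in the 3 wild-type libraries of each population, on a log axis, for 19 lists. Endothelial lists stand highest in endothelial libraries (pan-endothelial, 836 CPM), alveolar lists in epithelial libraries (type 2, 2001 CPM) and the fibroblast list in triple-negative libraries (662 CPM).

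Of 15448 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 9693 differed between endothelial and epithelial cells (4765 higher and 4928 lower in endothelial cells), 8983 between endothelial and triple-negative cells (4459 and 4524) and 7057 between triple-negative and epithelial cells (3631 and 3426). The 3426 lower genes of the last contrast became 1902 without epithelial replicate 3 and 2265 without epithelial replicate 1. Higher than in both other populations were 2496 genes in epithelial, 3389 in endothelial and 1448 in triple-negative cells. By the smaller of both log2 differences, epithelial cells were led by Acoxl (142 ± 48.1 CPM), Rprm (16.6 ± 2.91), Rbpjl (144 ± 14.9), the complement gene Hc (2094 ± 423) and Sp5 (14.2 ± 6.06). Their differences between endothelial and triple-negative cells were smaller, from -1.52 for Acoxl to -1.94 for Rprm. Endothelial cells were led by Cyp1a1 (32.4 ± 27.3 CPM), the incretin receptor Glp1r (62.7 ± 3.72), Clca1 (48.9 ± 4.22), Sema3g (513 ± 105) and Clec14a (546 ± 112). Triple-negative cells were led by Sult1e1 (20.2 ± 26.3 CPM), the muscle oxygen carrier Mb (21.0 ± 34.4), the proteoglycan Lum (341 ± 271), Ebf2 (18.7 ± 16.2) and Pi16 (693 ± 565). The Mb and Sult1e1 values rested on wild-type replicate 3, which held 58.1 and 48.3 CPM of them. The same library held 129 CPM of the atrial myosin Myh6, whose difference from epithelial cells was 5.72, adjusted p = 0.0327 by edgeR, and 1.15 without that library, adjusted p = 0.247. Without any 1 of the 3 epithelial libraries the difference stayed as large (5.58 to 6.10), and the call was lost with adjusted p from 0.0848 to 0.10.

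Markers of other cell types were present in each sort. Epcam measured 221 ± 14.5 CPM in epithelial, 5.81 ± 3.37 in endothelial and 66.6 ± 73.1 in triple-negative wild-type libraries, and triple-negative and epithelial libraries did not differ past the threshold by edgeR (-1.73, adjusted p = 0.109). Triple-negative wild-type replicate 1 held 4149 Epcam counts against 939 and 247 in the other wild-type libraries. Pecam1 measured 22.3 ± 19.7, 2593 ± 112 and 259 ± 167 CPM in the same order. Ptprc, which encodes CD45, measured 86.2 ± 54.2, 9.94 ± 4.02 and 235 ± 89.3 CPM. Macrophage genes had list medians of 99.1 CPM in epithelial, 6.08 in endothelial and 185 in triple-negative libraries. Lyz2 measured 13881 ± 2848 CPM in epithelial, 333 ± 25.6 in endothelial and 7687 ± 5040 in triple-negative libraries. By their means, other abundant members ran in the opposite order between the epithelial and triple-negative sorts: Chi3l3 measured 2240 ± 1774 and 4589 ± 3741 CPM and Ccl6 547 ± 336 and 1195 ± 751 CPM. Neutrophil genes were lower (medians 6.59, 1.95 and 28.4 CPM), as were lymphocyte genes (1.19, 0.972 and 9.42 CPM). The difference of Ptprc between triple-negative and epithelial cells (1.45, adjusted p = 0.0480 by edgeR) was lost without epithelial replicate 1 (1.41, adjusted p = 0.118), epithelial replicate 3 (1.17, 0.102) or triple-negative replicate 2 (1.10, 0.147).

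The second comparison asked which genes differed between knockout and wild-type epithelial cells, the compartment that holds the tumour cells. The 4 genes with the lowest p values had higher levels in knockout cells: Il1r2, a decoy receptor of interleukin 1, measured 4.92 ± 0.32 CPM in wild-type and 11.03 ± 0.32 CPM in knockout libraries (1.16 ± 0.13), and Irg1, which makes itaconate in activated macrophages, 6.06 ± 1.33 and 21.6 ± 5.44 CPM (1.83 ± 0.26). The hyaluronan synthase Has1 measured 15.3 ± 3.15 and 30.7 ± 1.34 CPM (1.01 ± 0.16), and Csf3r, the receptor of granulocyte colony-stimulating factor, 8.70 ± 2.09 and 21.4 ± 2.12 CPM (1.30 ± 0.21). The kinase Ikbke was also higher by its estimate (0.64 ± 0.12), and the lowest p values among genes lower in knockout cells belonged to Mal (178 ± 6.42 and 132 ± 9.32 CPM, -0.43 ± 0.08), Bend7 (-0.32 ± 0.06), the ephrin Efna1 (-0.40 ± 0.09), Alpk3 (-1.12 ± 0.26) and Sh2d4a (-0.32 ± 0.08). None of these genes passed the main test: of 14787 genes, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, with 413 at an unadjusted p under 0.05. These were 2.79% of genes, against 4.28% in simulated libraries with no gene changed, so the count is no sign of a difference. DESeq2 called 8 (Il1r2, Irg1, Csf3r, Has1, S100a9, AB124611 and Slfn4 higher, Mal lower) and limma voom with sample weights called 0.

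The 33 gene lists were compared with all other genes by camera, which with its preset correlation of 0.01 called 14 lists in epithelial cells. With a correlation estimated per list camera called 0, and fry called 0. That form of camera rests on the few residual degrees of freedom of the libraries, so few lists could pass it. The neutrophil list had the largest median of the called lists, a log2 difference of 0.72, with 9 of 10 genes higher and 5 of them past the threshold adjusted over the list alone (0 over all genes); adjusted p = 1.8e-10 by camera and adjusted p = 0.065 with an estimated correlation. Its most significant genes were Il1r2, Csf3r and the calgranulin S100a9 (8.68 ± 2.28 and 36.8 ± 19.7 CPM, 2.08 ± 0.48). Its summed level was 136 ± 39.4 CPM in wild-type and 185 ± 39.0 CPM in knockout libraries, an exact two-sided permutation p of 0.3, where 0.1 is the smallest that 3 against 3 can give. Ltf weighed most in the wild-type sum (73.1 ± 35.1 CPM in the population fit) and was lower in triple-negative libraries (30.3 ± 17.9). By their means S100a9 and Csf3r ran the other way, so the sum is an uncertain measure of neutrophil RNA. Fibroblast and matrix genes had a median of 0.43 with 26 of 30 higher (Fbln1 0.74 ± 0.23, Mfap4 0.76 ± 0.34), camera adjusted p = 1.6e-07 and adjusted p = 0.828 with an estimated correlation. Genes of RAS to MAPK output, which respond to the pathway that oncogenic Kras drives, had a median of -0.21 with 14 of 20 lower, camera adjusted p = 1.1e-05 and adjusted p = 0.105 with an estimated correlation. Ereg (118 ± 16.3 and 88.1 ± 6.76 CPM, -0.42 ± 0.12) and the ERK phosphatase Dusp6 (231 ± 20.8 and 187 ± 7.84 CPM, -0.30 ± 0.09) had its lowest p values. No gene of these last lists passed the threshold adjusted over its list alone.

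The other 11 epithelial calls depended on single libraries, and each had adjusted p = 0.828 with an estimated correlation. Junction and keratin genes (median -0.18, 17 of 18 lower, camera adjusted p = 3.2e-06) and inflammatory genes (0.51, 22 of 24 higher, 3.2e-06; Ccl7 0.96 ± 0.33, Ccl2 1.02 ± 0.40) were both lost without knockout replicate 1, with medians of -0.03 and 0.06. Pan-endothelial genes (0.46, camera adjusted p = 5.3e-04), lung capillary genes (0.44, 0.00308) and smooth muscle genes (0.29, 0.00308) were lost without wild-type replicate 3 (-0.04, 0.04 and 0.02) or knockout replicate 1 (0.02, 0.04 and 0.22), smooth muscle also without knockout replicate 3 (0.02). Lymphocyte genes (0.17, camera adjusted p = 0.0126) were lost without either of those first libraries (-0.09 and 0.02) or wild-type replicate 1 (0.02). Mitosis genes (-0.14, camera adjusted p = 1.7e-04) were lost without knockout replicate 2 (0.01), hypoxia and glycolysis genes (-0.16, 8.0e-04) without the same library (-0.13) or wild-type replicate 1 (-0.07), and interferon genes (0.19, 4.2e-04) without wild-type replicate 1 (0.12). Alveolar type 2 genes (-0.10, camera adjusted p = 0.0112) were lost without knockout replicate 2 (-0.08) and turned to 0.05 without wild-type replicate 3. Alveolar type 1 genes (-0.15, 0.00441) were lost without wild-type replicate 1 (-0.06), wild-type replicate 2 (-0.13) or knockout replicate 1 (-0.19). Macrophage genes had a median of 0.41 (camera adjusted p = 0.409), with 46038 summed CPM in knockout replicate 1 against 13406 to 24332 in the other 5 libraries.

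The third comparison asked which endothelial genes differed without the cluster, the series title placing its effect in the formation of new vessels. The 5 genes with the lowest p values had lower levels in knockout endothelial cells, among them Rrm2 of the DNA replication list and Kif23, Bub1 and Cdc20 of the mitosis list. Stil, needed for centriole duplication, measured 4.93 ± 0.85 CPM in wild-type and 1.76 ± 0.23 CPM in knockout libraries (-1.48 ± 0.23). The ribonucleotide reductase subunit Rrm2 measured 11.1 ± 2.70 and 5.07 ± 0.81 CPM (-1.13 ± 0.22), the mitotic kinesin Kif23 11.1 ± 1.55 and 6.05 ± 0.96 CPM (-0.87 ± 0.18), the checkpoint kinase Bub1 4.54 ± 0.84 and 1.91 ± 0.39 CPM (-1.24 ± 0.26) and the anaphase activator Cdc20 11.4 ± 1.36 and 6.45 ± 1.10 CPM (-0.82 ± 0.17). The 5 lowest p values among genes higher in knockout cells belonged to Ccdc135 (1.60 ± 0.34), the serpin Serpina3g (41.9 ± 5.16 and 83.9 ± 23.0 CPM, 0.999 ± 0.209), Hpcal4 (1.03 ± 0.23), Slc24a4 (0.37 ± 0.09) and Scube1 (0.44 ± 0.12). As single genes none passed: of 13849 genes, edgeR's quasi-likelihood test called 0, with 296 at an unadjusted p under 0.05 (2.14%, against 4.89% in simulated libraries with no gene changed). DESeq2 called 1, Stil (adjusted p = 0.00855), and limma voom called 0. Without knockout replicate 3 edgeR called 1 gene, Amd1, whose estimate was 352 counts in both remaining knockout libraries and 0 in all wild-type libraries, a repeated value treated as uncertain.

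As a group, mitosis genes were lower in knockout endothelial cells in all 34 members, with a median of -0.94, and 30 of the 34 passed the threshold adjusted over the list alone (0 over all genes). Camera gave adjusted p = 2.8e-74 with its preset correlation and adjusted p = 0.407 with an estimated correlation. Summed over the list, the level was 366 ± 81.3 CPM in wild-type and 199 ± 48.4 CPM in knockout libraries, with 284 as the lowest wild-type and 255 as the highest knockout value (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Single members ran from -1.30 ± 0.36 for the kinetochore gene Cenpf to -0.28 ± 0.11 for Ncaph, and the proliferation marker Mki67 differed by -1.06 ± 0.27. The median lay between -0.73 (without wild-type replicate 2) and -1.26 (without knockout replicate 2) when single libraries were left out. DNA replication genes had a median of -0.40 with 31 of 32 lower and 1, Rrm2, past the threshold adjusted over the list alone (0 over all genes); camera adjusted p = 4.3e-19 and adjusted p = 0.462 with an estimated correlation. Their summed level was 625 ± 110 and 542 ± 21.4 CPM (exact permutation p = 0.2). In epithelial cells summed mitosis levels were 269 ± 32.4 and 249 ± 34.1 CPM (exact permutation p = 0.5), and in triple-negative cells 294 ± 76.0 and 309 ± 126 CPM (exact permutation p = 0.9).

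**Figure D2:**
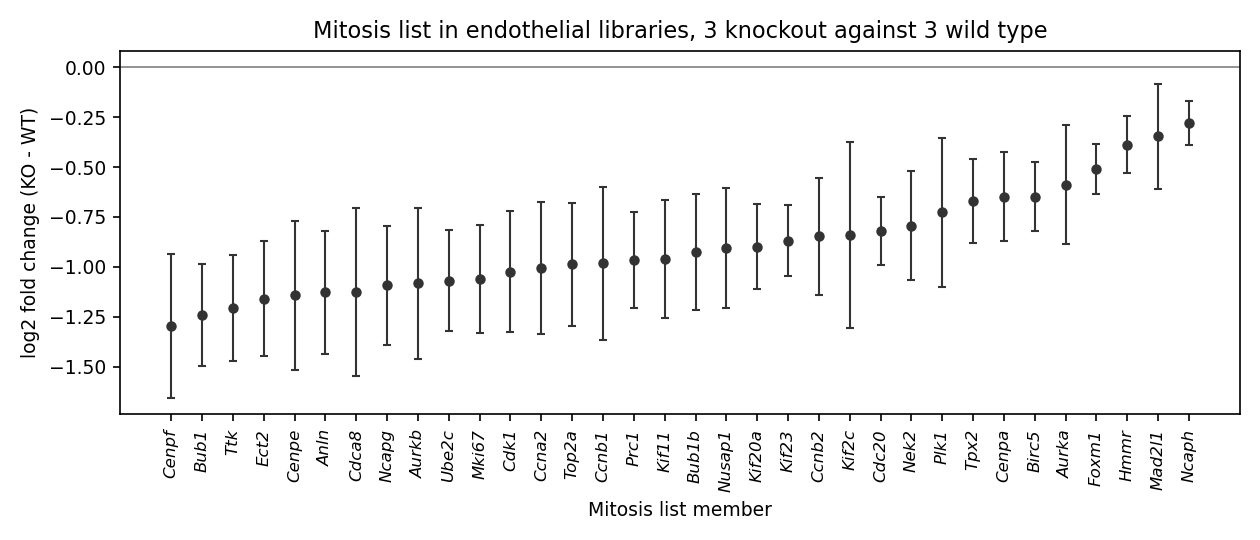
Log2 fold change (knockout minus wild type) of the 34 mitosis genes in endothelial cells; points are estimates and whiskers are ± SE from edgeR's fit to 3 libraries per genotype. All 34 lie below 0, from -1.30 for Cenpf to -0.28 for Ncaph.

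Of the remaining vascular lists, angiogenesis and tip cell genes had a median of -0.15 in knockout endothelial cells with 21 of 32 lower, camera adjusted p = 5.8e-04 and adjusted p = 0.506 with an estimated correlation; the call was lost without knockout replicate 1 (median -0.01). The tip cell peptide gene Apln measured 128 ± 7.78 and 84.6 ± 18.4 CPM (-0.59 ± 0.16), the Tie2 ligand Angpt2 76.1 ± 18.5 and 54.0 ± 6.59 CPM (-0.50 ± 0.18) and the VEGF co-receptor Nrp2 401 ± 50.2 and 306 ± 49.97 CPM (-0.39 ± 0.16), none past the threshold adjusted over the list alone. Lung capillary genes had a median of 0.18 with 10 of 12 higher (Kit 0.28 ± 0.13, Cd93 0.25 ± 0.11), camera adjusted p = 0.00277 and adjusted p = 0.407 with an estimated correlation, lost without knockout replicate 1 (0.10). Pan-endothelial genes were not called (median 0.04, camera adjusted p = 0.135), nor were lymphatic genes (-0.23, 0.622). Interferon genes had a median of 0.22 with 30 of 31 higher (Oas1a 0.40 ± 0.17, Irf7 0.24 ± 0.11), camera adjusted p = 9.0e-10 and adjusted p = 0.506 with an estimated correlation. Inflammatory genes had a median of 0.32 with 22 of 23 higher (Il6 0.32 ± 0.13, Cxcl2 0.49 ± 0.20), camera adjusted p = 2.0e-08 and adjusted p = 0.407 with an estimated correlation. Hypoxia and glycolysis genes had a median of -0.31 with 20 of 23 lower, camera adjusted p = 9.1e-08 and adjusted p = 0.599 with an estimated correlation, although the lowest p value in the list was that of Pfkfb3, a glycolytic regulator that was higher (0.46 ± 0.20).

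Camera called 13 of 32 lists in endothelial cells, again 0 with an estimated correlation and 0 with fry, and 20 without knockout replicate 3. The other 6 depended on single libraries. Junction and keratin genes (median -0.44, camera adjusted p = 5.4e-04) turned to 0.05 without wild-type replicate 1 and were lost without knockout replicate 3 (-0.21), and alveolar type 2 genes (-0.28, 5.8e-05) were lost without wild-type replicate 1 (-0.09). Macrophage genes (0.57, camera adjusted p = 0.00105) turned to -0.17 without knockout replicate 3, which held 2344 summed CPM against 383 to 736 in the other 5 libraries, and were lost without wild-type replicate 3 (0.74). Pan-leukocyte genes (0.39, 1.3e-04) were lost without wild-type replicate 3 (0.16), and neutrophil genes (0.74, 0.00277) and immediate early genes (0.21, 3.2e-05) without wild-type replicate 3 (0.58 and 0.11) or knockout replicate 1 (0.36 and 0.07). With the replicate number as a block, 16 lists were called: the same 13 with pericyte genes (-0.14, camera adjusted p = 0.106; blocked -0.32, 0.00815), lymphocyte genes (0.35, 0.106; blocked 0.27, 0.0465) and mesothelium genes (0.72, 0.0722; blocked 0.48, 1.2e-04) added. Without the block and with an estimated correlation, adjusted p was 0.775 for each of these 3 lists. With an estimated correlation, the adjusted p was 0.407 for pan-leukocyte genes and 0.657 for the other 5 of the 6 calls that depended on single libraries.

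The fourth comparison asked which genes differed in triple-negative cells, where mesenchymal genes were highest. The largest differences included Il5, a cytokine that acts on eosinophils, at 0.13 ± 0.14 CPM in wild-type and 2.40 ± 0.23 CPM in knockout libraries (4.10 ± 0.71). Arhgef37 measured 0.27 ± 0.10 and 2.20 ± 0.71 CPM (2.97 ± 0.48). This gene lies on chromosome 18 as the second protein-coding gene on one side of the deleted cluster, and it was the 1 of 20 tested cluster neighbours past the threshold adjusted over that list alone (0 over all genes). In epithelial cells it measured 0.41 ± 0.09 and 0.94 ± 0.36 CPM (1.17 ± 0.41). The cation channel Trpm2 (7.33 ± 0.81 and 19.0 ± 3.89 CPM, 1.37 ± 0.22), Emr4 (1.58 ± 0.27) and Cd300lb (1.51 ± 0.28), all known from myeloid cells, had the other lowest p values among genes that were higher in knockout cells and met the naming rule. Lower were the cartilage collagen Col2a1 (3.72 ± 0.57 and 0.48 ± 0.31 CPM, -2.94 ± 0.60), the receptor tyrosine kinase Ret (10.2 ± 0.74 and 3.99 ± 1.27 CPM, -1.35 ± 0.30), the neurotrophin receptor Ntrk2 (133 ± 19.3 and 75.3 ± 16.2 CPM, -0.82 ± 0.21), Krtap17-1 (-2.45 ± 0.65) and Dynlt1a (-0.90 ± 0.24). Of 15311 genes, edgeR's quasi-likelihood test called 0, with 213 at an unadjusted p under 0.05 (1.39%, against 4.54% in simulated libraries with no gene changed). DESeq2 called 17, of which 15 were higher and 2, Col2a1 and Ret, lower; Il5, Arhgef37, Trpm2, Emr4, Cd300lb and the neutrophil gene Retnlg were among the 15. Limma voom called 0.

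Neutrophil genes were higher as a group in knockout triple-negative cells, with a median of 1.24 and 10 of 11 genes higher, camera adjusted p = 2.2e-19 and adjusted p = 0.185 with an estimated correlation. Of the list, 0 genes passed the threshold adjusted over the list alone. Wild-type replicates 1 and 2 with knockout replicate 2, set against wild-type replicate 3 with knockout replicates 1 and 3, gave a larger median of 1.41. That split mixes the genotypes but keeps most libraries of each genotype together, so it is not independent of genotype. Retnlg measured 3.20 ± 1.51 and 18.4 ± 11.7 CPM (2.52 ± 0.59), the calgranulin S100a8 30.2 ± 22.3 and 124 ± 51.7 CPM (2.04 ± 0.59) and the stefin Stfa2l1 0.58 ± 0.57 and 3.42 ± 1.75 CPM (2.58 ± 0.83). The summed level was 271 ± 181 CPM in wild-type and 775 ± 286 CPM in knockout libraries, with no overlap (exact two-sided permutation p = 0.1, the smallest possible). Inflammatory genes had a median of 0.34 with 23 of 24 higher (Cxcl2 321 ± 62.9 and 556 ± 72.0 CPM, 0.79 ± 0.23; Cxcl5 0.58 ± 0.18), camera adjusted p = 2.8e-09 and adjusted p = 0.374 with an estimated correlation. Interferon genes had a median of 0.24 with 30 of 31 higher (Oas3 0.84 ± 0.29), camera adjusted p = 3.3e-08 and adjusted p = 0.378 with an estimated correlation. Beside these, Ptprc measured 239 ± 90.4 and 317 ± 116 CPM (0.41 ± 0.38), and all 13 pan-leukocyte genes were higher (median 0.45, camera adjusted p = 3.3e-05, adjusted p = 0.574 with an estimated correlation), a call lost without knockout replicate 2 (0.00). The B-cell gene Igj measured 67.1 ± 11.5 and 177 ± 69.6 CPM (1.40 ± 0.34) in a lymphocyte list that was not called (median -0.17, mean 0.06).

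**Figure D3:**
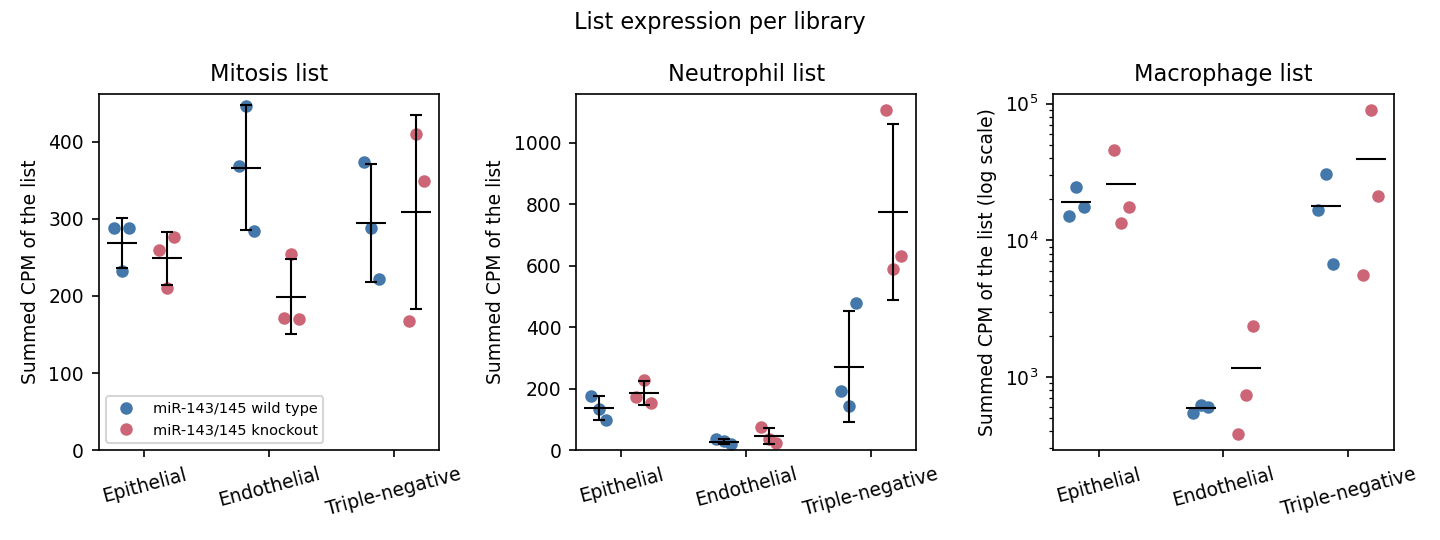
Summed CPM of the mitosis, neutrophil and macrophage lists in each of the 18 libraries; points are libraries, horizontal bars are means of 3, whiskers are ± SD (not drawn in the macrophage panel, which has a log axis). Endothelial mitosis sums were 284 to 447 CPM in wild-type and 170 to 255 CPM in knockout libraries, and triple-negative neutrophil sums 142.9 to 477 and 589 to 1105 CPM. Lyz2 (13881 ± 2848 CPM in wild-type epithelial libraries) makes up a large part of the epithelial macrophage sums.

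Camera called 16 of 33 lists in triple-negative cells, 0 with an estimated correlation and 0 with fry, and 10 without wild-type replicate 1. Epithelial lists did not all move together in knockout cells: airway genes were not called, with a median of 0.04, a mean of -0.14 and 8 of 15 higher (camera adjusted p = 0.373). The other epithelial lists were lower, with 0 members past the threshold adjusted over the list alone: junction and keratin genes had a median of -1.04 with 18 of 18 lower (camera adjusted p = 4.3e-09), alveolar type 2 genes -0.85 (4.3e-09) and alveolar type 1 genes -0.57 (3.1e-04). Without wild-type replicate 1, which held 718 CPM of Krt18 against 120 and 55.9 in the other wild-type libraries, those medians were -0.02, -0.20 and -0.14 and all 3 calls were lost; the alveolar type 1 call was also lost without knockout replicate 2 (-0.38). Leaving out wild-type replicate 1 also ended the calls for RAS to MAPK output (-0.29, camera adjusted p = 0.00122; -0.09 without it), smooth muscle genes (0.30, 9.9e-04; 0.04) and red blood cell genes (1.18, 0.0244; 0.67), and turned lung adenocarcinoma progression genes (-0.21, 0.0353) to 0.09. Smooth muscle was lost without knockout replicate 1 too (0.14), red blood cell without wild-type replicate 3 (0.85) or knockout replicate 1 (-0.44), and adenocarcinoma progression without knockout replicate 2 (-0.20) or 3 (-0.22). Pericyte genes (-0.32, 0.0142) were lost without wild-type replicate 2 (-0.13) or 3 (-0.20) or knockout replicate 1 (-0.05) or 2 (-0.22), and angiogenesis genes (-0.21, 0.0353) without wild-type replicate 1 (-0.08) or 2 (-0.05) or knockout replicate 1 (-0.16) or 2 (-0.28).

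Fibroblast and matrix genes, most of which were highest in this sort among wild-type libraries, had a median of -0.19 with 28 of 30 lower (Col1a1 3794 ± 2867 and 2323 ± 938 CPM, -0.71 ± 0.63), camera adjusted p = 0.0353 and adjusted p = 0.848 with an estimated correlation. The median turned to 0.42 without wild-type replicate 3 (camera adjusted p = 0.00337) and to 0.12 without knockout replicate 2. Macrophage genes (0.52, 0.0353) were 0.19 without wild-type replicate 3 and -0.45 without knockout replicate 2, which held 90175 summed CPM against 5555 to 30282 in the other 5 libraries, and the call was lost without knockout replicate 3 (0.52). Immediate early genes (0.13, 0.0353) were 0.01 without wild-type replicate 2, -0.10 without knockout replicate 1 and 0.14, no longer called, without wild-type replicate 1. With an estimated correlation, adjusted p was 0.848 for macrophage and immediate early genes, 0.821 for smooth muscle, 0.732 for pericyte genes and 0.574 for the other lists called in these last paragraphs. Cardiac muscle genes, led by wild-type replicate 3, were lower in 10 of 10 members (median -1.53) and not called (camera adjusted p = 0.334).

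The lists of microRNA targets from the literature tested whether reported targets were higher without the cluster. The 25 miR-145 targets had medians of 0.05 in epithelial, -0.02 in endothelial and -0.02 in triple-negative cells (camera adjusted p = 0.992, 0.377 and 0.251). The 17 miR-143 targets had medians of 0.06, 0.02 and 0.03 (0.384, 0.797 and 0.815). For miR-145 in epithelial cells and miR-143 in triple-negative cells, camera's direction was downward although the median was positive. Genes with a 3′ UTR site matching the seed of miR-145-5p (AACTGGA) or miR-143-3p (TCATCTC) were tested more widely, with 1850 to 2013 and 1784 to 1951 site-bearing genes per population. Their median log2 differences were 0.03, 0.00 and 0.00 for miR-145 and 0.02, 0.00 and 0.00 for miR-143, in epithelial, endothelial and triple-negative cells, and camera gave an adjusted p of 0.926 for each of these 6 sets.

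The fifth comparison asked whether the genotype effect itself differed between populations, in a fit of all 18 libraries. The fit treated the libraries as independent, although with 3 mice per genotype the sorts can share mice. Among genes that met the naming rule, Stil had the lowest p between endothelial and triple-negative cells, with a difference of -1.95 ± 0.46 (-1.48 and 0.47 in each). It was followed there by Dars2 (-0.69 ± 0.19), the lactate exporter Slc16a3 (-1.45 ± 0.41), Bub1 (-1.91 ± 0.55) and the cell cycle factor E2f8 (-1.75 ± 0.53). Between endothelial and epithelial cells the order was Armcx6 (-1.36 ± 0.41), Nxn (-1.09 ± 0.34), Tnfsf11 (-4.50 ± 1.40), Fanca (-1.49 ± 0.49) and Stil (-1.38 ± 0.46). Between triple-negative and epithelial cells it was Klk8 (-1.15 ± 0.25), Rgs4 (-1.15 ± 0.35), Alb (-3.78 ± 1.27), Sema6a (-0.91 ± 0.31) and Cytl1 (-3.17 ± 1.11). No gene passed: of 15924 genes, edgeR's quasi-likelihood test called 0 in each contrast, with 118, 204 and 106 genes (0.741%, 1.28% and 0.666%) at an unadjusted p under 0.05 for endothelial against epithelial, endothelial against triple-negative and triple-negative against epithelial cells. DESeq2 called 1 gene in each, Gm9781, Amd1 and Gm9781, both of which carry the same non-whole estimate in several libraries and are treated as uncertain.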

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

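The tests of carried-over RNA, of Xist against replicate numbers and of the macrophage order, and the list tests of a difference between populations, were chosen only after the results were seen.

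Cell division genes were lower in knockout endothelial cells by more than in the other sorts: the median difference of the mitosis list in genotype effect was -0.75 between endothelial and epithelial cells (all 34 genes negative, camera adjusted p = 2.7e-22) and -0.98 between endothelial and triple-negative cells (3.2e-36), with adjusted p = 0.945 and 0.335 under an estimated correlation. Epithelial and triple-negative cells gave an estimated 1.04% to 3.68% and 1.36% to 5.82% of the RNA in endothelial libraries, which carries at most 23.8 CPM of mitosis RNA into any of them, or 13.6% of the fall of 175 CPM in the summed level (372 ± 85.6 to 197 ± 55.8 CPM by plain totals, SD, n = 3), too little to make the difference. The Xist-positive library (knockout replicate 3) was not needed for it either, since the median was -0.82 without it against -0.94 with it. Of the 10 splits of the 6 libraries only the real one (1 of 10) gave a median of that size, the highest other being 0.81 in size, and the other 3 splits that part all same-numbered pairs gave -0.49, -0.19 and 0.21; 10 splits are too few for a share under 0.05. A lower rate of division in endothelial cells without the cluster stays open as a hypothesis, beside a grouping of these 6 libraries that is unrelated to genotype. Causes other than those named here were not tested.

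Neutrophil genes were higher in knockout than wild-type triple-negative cells by camera at its preset correlation (median 1.24, adjusted p = 0.185 with an estimated correlation and 0.714 with fry). They were also higher in epithelial cells (0.72, with 0.065 and 0.0871). In triple-negative cells their abundant members S100a9 (41.8 ± 41.7 and 234 ± 153 CPM) and Csf3r (48.9 ± 52.9 and 139 ± 42.1 CPM) stayed far below Lyz2 of the macrophage list (7687 ± 5040 CPM in wild-type libraries). Lyz2 was higher still in wild-type epithelial libraries (13881 ± 2848 CPM), unlike Chi3l3 and Ccl6, so its level is an uncertain measure of macrophage RNA. A sort against CD45 should remove neutrophils from the triple-negative cells, and no gene of the neutrophil list is in another list. A greater carry-over of CD45-positive cells of every kind would raise macrophage and lymphocyte genes alike; the difference of the neutrophil score exceeded the mean of theirs by 1.469 in triple-negative and 0.5412 in epithelial cells, inside the spreads of 2.272 and 1.521, so carry-over of all leukocytes and a change in neutrophils alone cannot be told apart with 3 libraries per group. The Xist-positive libraries did not make the difference, as the median was 1.51 without knockout replicate 2 in triple-negative cells and 0.78 without knockout replicate 1 in epithelial cells. Among other splits of the triple-negative libraries, that of wild-type replicates 1 and 2 with knockout replicate 2 gave a larger median, 1.41. In epithelial cells no other split gave a median as large in size, the farthest from 0 being -0.42. More neutrophils in the knockout lungs may be 1 source, and no value here separates it from a looser sort or from a grouping of the libraries unrelated to genotype.

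Xist, the RNA of the inactive X chromosome, was tested as a single gene and not called for genotype (unadjusted p = 0.0417, 0.0243 and 0.0584 by edgeR in epithelial, endothelial and triple-negative cells, adjusted p = 1.0 in each), was in no list that entered a set test, and had 16604 counts in epithelial knockout replicate 1, 17729 in endothelial knockout replicate 3 and 18805 in triple-negative knockout replicate 2, against 6 to 152 in the other 15 libraries, while the Y-linked Ddx3y had 7, 0 and 11 counts there and 1493 to 4740 elsewhere. A number that named the same mouse in every population is excluded, since all 3 knockout numbers had both an Xist-positive and a Y-positive library. A single Xist-positive knockout mouse carrying other numbers in each sort is a candidate explanation, with exactly 1 such library in each of 3 populations; deviations from the group means correlated across genes between these libraries (0.558, 0.322 and 0.447), and so they did in epithelial 2, endothelial 1 and triple-negative 1 (0.546, 0.279 and 0.369) and in epithelial 3, endothelial 2 and triple-negative 3 (0.292, 0.41 and 0.507) of the knockout, which is consistent with mice shared across sorts, although such values depend on each other in groups of 3 and genes are not independent replicates. The macrophage list was highest in the Xist-positive library in 3 of 3 populations, with 46038, 2344 and 90175 summed CPM, and Chi3l3, a chitinase-like protein of alveolar macrophages, reached 19100, 1261 and 50490 CPM there against 643 to 4199, 30.8 to 182 and 1104 to 9257 CPM elsewhere. By chance order, independent in the 3 populations, this has a probability of 0.00463 for 1 list and 0.148 over the 32 lists looked at. If the Xist-positive libraries came from 1 mouse, the orders would not be independent and the probability would be higher. Sex, macrophage content and chance therefore cannot be told apart with 1 such library per population.

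The remaining differences in genotype effect between populations were tested for each list in the fit of all 18 libraries, and are given as medians, each with an adjusted p by camera at its preset correlation. Between endothelial and epithelial cells they were -0.40 for pan-endothelial (0.00156), -0.23 for angiogenesis and tip cell (0.0368), -0.27 for fibroblast and matrix (0.0396), -0.49 for platelet (0.0272) and -0.27 for DNA replication genes (1.2e-07), each with adjusted p = 0.945 under an estimated correlation. Between endothelial and triple-negative cells they were 0.66 for alveolar type 2 (2.0e-04), 0.80 for alveolar type 1 (4.6e-05), 0.76 for junction and keratin (0.00774) and -0.42 for neutrophil genes (0.00500), each with adjusted p = 0.992 under an estimated correlation, and -0.48 for DNA replication genes (1.1e-17), with 0.355. Between triple-negative and epithelial cells they were -0.70 for pan-endothelial (6.9e-06), -0.55 for lung capillary (0.0124), -0.60 for fibroblast and matrix (2.3e-05), -0.79 for alveolar type 2 (6.0e-07), -0.45 for alveolar type 1 (0.0375), -0.94 for junction and keratin (8.8e-05), 0.37 for neutrophil (3.0e-05), 0.18 for mitosis (0.00117) and 0.13 for DNA replication genes (7.5e-04), each with adjusted p = 0.943 under an estimated correlation.

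Other splits of the libraries were fitted in the same way. With 10 splits per comparison a share under 0.05 cannot be reached, and only the real value and the highest other are given. Populations gave 9693, 8983 and 7057 genes in the real split (1 of 10 in each) and 0 in the highest other. Genotype gave 0 genes by edgeR in each population (413, 296 and 213 at an unadjusted p under 0.05), so 10 of 10 splits had to give as many and the comparison carries no information, the highest others being 0, 3 and 1 in epithelial, endothelial and triple-negative cells. Lists called were 14, 13 and 16 in the real splits against 18, 19 and 24 in the highest others, with 9, 10 and 5 of 10 splits calling as many. The endothelial splits that part all 3 pairs called 13 (the real one), 18, 15 and 19 lists. For the difference of genotype effects, the real count was also 0, so 100 of 100 shuffles had to give as many and nothing follows about chance; the highest others were 2, 59 and 1138 for endothelial against epithelial, endothelial against triple-negative and triple-negative against epithelial cells. The shuffles with 1138 and 935 genes both set epithelial wild-type replicate 2 with knockout replicates 1 and 3, and triple-negative wild-type replicate 3 with knockout replicates 1 and 3. The real labels gave 0 genes, so these counts point to a structure of the samples that does not follow genotype alone. Both shuffles still kept most knockout libraries of these populations together, so they are not independent of genotype.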

How the results depend on the processing

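Leaving out the 3 Xist-positive libraries together was added after the data had been seen. Population differences kept within 1.5 times their total number of genes in every alternative run: 9693, 8983 and 7057 genes became 9308, 8402 and 6071 in knockout libraries, 7691, 6661 and 5509 under the stricter filter, where fewer genes were tested, 10419, 9514 and 8007 with DESeq2, and 8614 to 8934, 7656 to 8578 and 4884 to 7053 without single libraries. By direction, genes lower in triple-negative than epithelial cells went beyond that bound, from 3426 to 1902 without epithelial replicate 3 and 2265 without epithelial replicate 1. Plain library size shifted the median of all genes by -0.14, -0.13 and -0.01 and lowered the share of higher calls in endothelial cells from 49.2% to 41.8% against epithelial and from 49.6% to 40.5% against triple-negative cells; for 51.5% in triple-negative against epithelial cells it gave 51.2%. For genotype, edgeR called 0 genes in each population under DESeq2 size factors, no filter, the stricter filter and all 18 libraries in 1 fit, and limma voom 0. The DESeq2 Wald test called 8, 1 and 17 genes in epithelial, endothelial and triple-negative cells, and 1, 1 and 1 in the differences between populations (Gm9781 or Amd1, with repeated estimates); the cause was not tested. Leaving out single libraries gave 0 to 1 genes in endothelial cells (Amd1 without knockout replicate 3) and 0 in the other populations. The differences of genotype effect had 0 genes without the 3 Xist-positive libraries.

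List calls depended most on the form of the list test: the 14, 13 and 16 calls became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. Higher correlation was not the whole reason, since the epithelial neutrophil and RAS to MAPK lists had estimates of -0.0219 and -0.0106, below the preset 0.01. Their camera adjusted p still went from 1.8e-10 to 0.065 and from 1.1e-05 to 0.105. With an estimated correlation, camera takes its p values from the few residual degrees of freedom of the libraries, which leaves little room to pass. The neutrophil list reached an unadjusted p of only 0.00197 that way. Finding 0 calls there does not show that a list difference is absent, and it gives no support to the calls at the preset correlation. The endothelial mitosis median stayed at -0.94 with an estimated correlation and with fry (adjusted p = 0.407 and 0.832), since neither changes the fold changes, and lay between -0.73 and -1.26 without single libraries. Such omissions gave 11 to 20 lists in epithelial, 12 to 20 in endothelial and 10 to 23 in triple-negative cells. Called lists whose camera direction turned had these ranges: pan-endothelial -0.038 to 1.11 and alveolar type 2 -0.22 to 0.046 in epithelial cells; junction and keratin -0.76 to 0.047 and macrophage -0.17 to 0.80 in endothelial cells. In triple-negative cells the ranges were -0.46 to 0.42 for fibroblast (0.12 without knockout replicate 2), -0.42 to 0.092 for adenocarcinoma progression, -0.10 to 0.34 for immediate early (0.01 without wild-type replicate 2, camera's direction turning) and -0.45 to 1.09 for macrophage genes (0.19 without wild-type replicate 3, likewise). In lymphocyte (-0.09) and mitosis (0.0056) genes of epithelial cells and red blood cell genes of triple-negative cells (-0.44) the median alone changed sign, without wild-type replicate 3, knockout replicate 2 and knockout replicate 1. Which trait of a library made these changes was not tested. Over 477 other results and 5675 alternatives, 5329 kept direction and side of the threshold, 67 passed it only in the alternative, 268 no longer passed and 11 reversed.

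A knockout number did not name the same mouse in every population, so a block on it does not test for mice shared across sorts. With the replicate number as a block, genes called were 0, 0 and 0 for genotype, 0, 0 and 0 for its difference between populations and 9483, 8661 and 6956 for populations, and the endothelial mitosis median was -0.97 (adjusted p = 7.5e-105 by camera at its preset correlation; without the block it was 0.407 with an estimated correlation and 0.832 with fry). Lists called became 16, 16 and 13: epithelial cells gained red blood cell (0.82, adjusted p = 0.0185) and mesothelium genes (0.27, 0.0182), which had adjusted p = 0.828 and 0.920 without the block and with an estimated correlation. Triple-negative cells lost immediate early (0.11, 0.0512), macrophage (0.27, 0.0828) and red blood cell genes (0.28, 0.0538). Outside the endothelial comparison the numbers did not pair libraries (correlations of -0.0232, -0.584 and 0.276 in epithelial and -0.114, 0.551 and 0.24 in triple-negative cells), and not every library correlated best with its own number. In endothelial cells too, wild-type replicates 1 and 2 each correlated best with another knockout number (0.255 and 0.317), so the pairing there is uncertain. Depth limits low genes, 3 counts being 0.0976 to 0.171 CPM. Simulated changes of log2 1 were recovered in 4.5% of genes in triple-negative and 61.2% in endothelial cells, although triple-negative libraries were not shallower on average. The simulated populations differed only in means, dispersions and library sizes. Triple-negative libraries of a group differed more from each other, with a chi-square per gene of 101 to 414 against 21.1 to 74.2 in endothelial pairs. A larger spread between libraries therefore goes with the lower recovery.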

Other observations

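The tests of seed-site genes against a shift of 0.1 were chosen only after the result was seen, and the genes described first were chosen after their values were seen.

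The endothelial sort held lymphatic vessel genes. In wild-type libraries the chemokine gene Ccl21a measured 1401 ± 907 CPM, the hyaluronan receptor Lyve1 596 ± 186 CPM, the lymphatic growth factor receptor Flt4 399 ± 149 CPM and Reln 145 ± 104 CPM (SD, n = 3), against 6.46 ± 8.83, 4.35 ± 3.09, 2.76 ± 2.64 and 0.53 ± 0.33 CPM in epithelial libraries. Triple-negative libraries held more than epithelial ones, with Ccl21a at 321 ± 406 and Lyve1 at 59.3 ± 46.0 CPM. In endothelial libraries the spread of these lymphatic genes was larger than that of the pan-endothelial gene Cdh5 (3275 ± 49.6 CPM). Other pan-endothelial genes varied more than Cdh5 there, such as Vwf (3554 ± 1034 CPM) and Ptprb (3131 ± 393 CPM), so a large spread was not particular to lymphatic genes. Genes from lists of other cell types were also highest in this sort: Prx, placed in the Schwann list for its role in myelin, measured 771 ± 195 CPM against 13.9 ± 5.15 in epithelial and 82.0 ± 40.1 in triple-negative cells, and the blood and endothelial transcription factor Tal1, placed in the red blood cell list, 131 ± 7.14 CPM against 1.34 ± 1.38 and 15.8 ± 9.70. Zeb1 and Serpine1, from the list of mesenchymal transition, measured 206 ± 1.94 and 1413 ± 170 CPM in endothelial, 98.2 ± 26.8 and 736 ± 199 in triple-negative and 10.7 ± 3.73 and 179 ± 63.3 in epithelial cells. All of these passed edgeR's test in both endothelial contrasts except Ccl21a against triple-negative cells (adjusted p = 0.186).

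Cd74, the invariant chain of class II antigen presentation, measured 4238 ± 780 CPM in epithelial, 2388 ± 483 in endothelial and 2570 ± 1560 in triple-negative wild-type cells, with no contrast past the threshold (adjusted p = 0.164, 0.866 and 0.249 by edgeR). Its transcriptional activator Ciita measured 52.8 ± 5.13, 113 ± 34.7 and 25.2 ± 14.7 CPM in that order, and endothelial and triple-negative cells differed (2.17, adjusted p = 0.00537 by edgeR). Complement C3 measured 7273 ± 5785 CPM in triple-negative, 787 ± 160 in epithelial and 92.6 ± 57.2 in endothelial cells and differed in every contrast. Between genotypes, class II genes had medians of -0.03, 0.12 and -0.04 in epithelial, endothelial and triple-negative cells (camera adjusted p = 0.909, 0.248 and 0.951), airway genes 0.48, 0.28 and 0.04 (0.992, 0.404 and 0.373), and genes of TGF-beta response and mesenchymal transition 0.12, 0.01 and 0.09 (0.331, 0.688 and 0.308). Platelet genes had medians of 0.27, 0.08 and 0.55 (0.287, 0.491 and 0.150), Schwann genes 0.33, 0.05 and 0.09 (0.366, 0.815 and 0.491) and neighbours of the cluster -0.00, 0.01 and 0.02 (0.992, 0.659 and 0.440). Lymphatic genes had 0.00 in epithelial and -0.83 in triple-negative cells (0.420 and 0.526).

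The lists not called and not yet given had these medians and camera adjusted p values. In epithelial cells they were 0.17 for angiogenesis (0.366), -0.06 for DNA replication (0.103), -0.46 for pericyte (0.117), 0.02 for adenocarcinoma progression (0.398), 0.10 for immediate early (0.103), 0.33 for pan-leukocyte (0.366), 1.06 for red blood cell (0.298), 0.56 for mesothelium (0.298) and -0.10 for cardiac genes (0.992). In endothelial cells they were 0.24 for smooth muscle (0.688), 0.16 for fibroblast (0.688), 0.15 for alveolar type 1 (0.253), -0.14 for adenocarcinoma progression (0.308), -0.08 for RAS to MAPK output (0.248) and 0.34 for red blood cell genes (0.106). In triple-negative cells they were -0.25 for pan-endothelial (0.389), 0.01 for lung capillary (0.777), 0.06 for mitosis (0.987), 0.08 for DNA replication (0.224), -0.15 for hypoxia (0.250) and -0.38 for mesothelium genes (0.440).

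A hypothesis tested here was that loss of the cluster raises genes with a seed site of miR-145-5p or miR-143-3p. After adjustment for 3′ UTR length and expression, site-bearing genes shifted by 0.0178 (miR-145-5p) and 0.00105 (miR-143-3p) in epithelial, 0.0057 and -0.00535 in endothelial and 0.00373 and 0.00672 in triple-negative cells. Of 100 shuffled heptamers, 7, 65, 18, 77, 64 and 44 gave a shift as high, so a small rise such as that in epithelial cells cannot be told apart from that of unrelated heptamers. An average rise of 0.1 was excluded, the highest shift being 0.0178 with a highest control SD of 0.0127, and in simulated data such a rise was estimated as 0.0934 to 0.113. Genes joined to a 3′ UTR made up 94.7%, 94.9% and 94.7% of those tested. Whether mature miR-143 and miR-145 were present in these sorted cells was not analysed here.

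Some estimates recur exactly between libraries. Amd1 had an estimate of 351.89 counts in endothelial knockout replicates 1 and 2 and triple-negative wild-type replicate 1 and 0 in the other 15 libraries, and Gm9781 had 56.43 in 6 libraries and 0 in 8. The other repeated estimates were 27.26 for Akr1b3, 33.7 for Atp6v0c, 43.55 for Btg3, 293.36 for Fam100b, 226.17 for Nutf2, 35.84 for Rmnd1 and 37.4 for Rpl34-ps1. The stress genes Hspa1b and Hspa1a ran from 4025 to 8585 and 3227 to 7272 CPM over the 18 libraries.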
